A study of Mus musculus with 158 samples.

How the data were processed

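The data were gene counts from the RNA of mouse brain cells, each collected by patch pipette and given no treatment. Per the series description, the RNA was amplified in 3 rounds of antisense RNA amplification before sequencing. Per the labels, libraries were made with the Illumina TruSeq Stranded kit from polyA RNA. The authors converted base calls with bcl2fastq 1.8.4 or bcl2fastq2 2.17, as stated for each sample, aligned reads with STAR and counted reads per gene with HTSeq, per the submitters' processing notes, against mm10 (GRCm38). Versions of STAR and HTSeq, the strand setting of the counting and the annotation used are not given in the sources used here. The deposited table holds raw counts of reads per gene, with no normalization by the authors, for 21956 gene rows and 158 libraries, and each column held whole numbers.

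Each library was assigned to a group from the sample labels alone. The plan counted each library as a cell, with libraries of repeated titles left out as an alternative. In 8 pairs of libraries the titles differed by an added b or _2, and 1 further pair of cultured cortical neuron libraries was recognised from the counts. The titles of this pair share the prefix J6 but differ in what follows, 8min_20 and 4min_9. The libraries of these 9 pairs correlated with r of 0.945 to 0.999 across genes (log2 CPM), against at most 0.621 with any other library, and shared 67.4% to 93.1% of their detected genes. No label marks the J6 pair as the same cell or explains the minutes, and its libraries differed by a chi-squared of 119.6 per degree of freedom, against 1.14 to 23.9 in the others. The counts of all 9 pairs were therefore summed, a choice made after the counts had been seen, which left 149 cells. In 3 of the pairs the libraries differed in basecalling version, with r of at least 0.973, and such a cell entered the analyses of each version with the library of that version. As the labels name no animal, donor or culture, cells were not treated as replicates, each group counted as 1 sample, and no test, p-value, standard error or number of differing genes is given.

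Counts were summed over the cells of a group and divided by the group's total over all rows, in counts per 1000000 (CPM). Summed counts had exact Poisson 95% intervals. For detection, each cell was thinned at random without replacement (seed 7) to the largest of 50000, 100000, 200000, 500000 and 1000000 counts that at least 90% of the cells of every group reached, which was 1000000. Genes with at least 5 counts there were called detected, and shares of cells had Clopper-Pearson 95% intervals. A gene was measured in a comparison when it had at least 10 counts in both groups together and at least 1 count in at least 3 cells. Log2 ratios used a pseudocount of 1 CPM. Where a group had no count, the fold was computed against a floor of 3 counts over the group, and setting such genes to that bound moved list medians by at most 0.0748 log2. The depth of the groups, from 27452025 summed counts in CA3 to 1275296188 in astrocytes, made counting error small beside the difference between cells, which the detection shares show.

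The genes named in a comparison had at least 10 CPM in a group and a log2 ratio of at least 1 in size in the summed CPM and in the mean of the cells' CPM. Both had to point the same way as the difference in detection, which also had to hold within each basecalling version with at least 3 cells of both groups. The 10 genes per direction with the largest difference in detection were taken, with predicted genes passed over. For the comparison of culture ages the number was lowered to 4 when the report was written, after the results had been seen. Gene lists of cell type markers and pathways, 31 in all, were fixed by hand from general knowledge, and members with the largest difference in detection serve as examples. The median log2 ratio of a list was set against 10000 random lists of the same size, drawn from 20 bins of like expression. Groups, comparisons, lists, the rule for named genes and the alternatives not named as added in the section on sensitivity were chosen before the data were examined.

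The 6 comparisons were astrocytes with neurons of cortical cultures, slice with cultured cortical neurons, CA1 with cortical and CA3 with CA1 slice neurons, hippocampal with cortical cultured neurons, and astrocytes of different culture ages. Alternatives tried were other weights of cells, edgeR TMM factors and DESeq2 size factors, pseudocounts of 0.1 and 5 CPM, other filters on low counts and other rules of detection. Others left out the deepest cells or repeat libraries, kept a single basecalling version or culture age, left out each CA3 cell in turn, or left out cells by their markers, by a title letter or by the share of their counts on 50 genes. On simulated data made from the slice and culture comparison (13671 genes, 200 of them changed by 2, 4 or 8 times), the direction was recovered for 98.5%, 100% and 100% of changed genes, and 68.7%, 67.2% and 66.7% of ratios lay within 0.5 log2 of the true value. Simulated lists of 20 genes made higher or lower lay above or below all random lists, and a list of unchanged genes above 41.01% of them. Both simulated groups had the same mean profile (dispersion 1), and only genes of at least 10 CPM were changed. Direction and error were scored after the median ratio of all genes was taken off, unlike the ratios reported here. The simulation held no mixed cell types and no gap in genes detected, so it does not give the accuracy of the real comparisons.

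Positions are from the RefSeq annotation of GRCm38.p6. Rows for the 13 mitochondrially encoded mRNAs were absent from the table, so the planned share of mitochondrial counts was not analysed here, nor was any variant. Some genes that the rules named are not reported here, and their ratios are left out of the sensitivity counts. The 27 rows with date-like names (0.307% of counts) stayed in the totals and are not named. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.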

Results

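Gene counts of 158 libraries, each made from the RNA of a mouse brain cell collected by patch pipette, were compared across 6 groups defined by cell type, brain region and source. After 9 libraries had been summed with another taken to be of the same cell, the groups held 86 cortical astrocytes, 13 cortical neurons and 8 hippocampal neurons from culture, and 22 cortical, 15 CA1 and 5 CA3 neurons from acute slices (149 cells). CA1 and CA3 are hippocampal fields. The astrocytes had been in culture for 7 days (3 cells), 12 days (70 cells), 14 days (5 cells) or 15 days (8 cells). The cultured cortical neurons had been kept for 6, 10 or 15 days (3 cells each) or 13 days (4 cells), and all 8 cultured hippocampal neurons for 15 days. The cultured cortical neurons of 6 and 15 days were basecalled with v1.8.4 and those of 10 and 13 days with v2.17. Values of these neurons within a single version are therefore also limited to those ages. The hippocampal cultures and the 7-day astrocytes carried the strain label C57/BL6, all other cells C57/BL6/N. The titles of 4 hippocampal libraries form 2 pairs that differ only in a last letter, S or D, which the labels do not explain. They were counted as 4 cells, and without the D libraries 6 hippocampal cells remain. No label named an animal, donor or culture, so cells were not counted as replicates: each group was 1 sample, no test of a difference was possible and none was made.

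Library totals ran from 535369 to 38680700 gene counts with a median of 10736000. Median totals per cell were 15369200 in cultured astrocytes, 13027000 in cultured cortical neurons, 10649000 in cultured hippocampal neurons, 5744560 in cortical slice neurons, 4125370 in CA1 neurons and 4916850 in CA3 neurons. Levels are given as counts summed over the cells of a group, in counts per 1000000 counts of the group (CPM), with the exact Poisson 95% interval in parentheses. Detection is given as the number of cells with at least 5 counts after every cell had been thinned to 1000000 counts, with the Clopper-Pearson 95% interval. The intervals, and the floors of 3 counts over a group used where a group had no count, cover counting error only, since reads without molecular identifiers are not independent molecules and cells of a group differed by more. Log2 ratios are of summed CPM plus 1. A CA1 cell with 535369 counts lay below the common depth and is missing from the detection shares, which leaves 14 CA1 cells there.

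At the common depth, cultured hippocampal neurons had the most genes detected, with a median of 7515.5 per cell (quartiles 5810.25 and 8018.25). The median was 4929.5 in astrocytes (3729 and 6749.75) and 4465 in cultured cortical neurons (1412 and 4925). Slice neurons had lower medians, 1819 in cortex (1031.75 and 3194.25), 1887 in CA1 (1661.75 and 2396) and 2159 in CA3 (2027 and 2280). The 50 highest genes of a cell held a median of 27.6%, 35.1% and 31.4% of its counts in those 3 slice groups, against 18.2% in astrocytes, 18.8% in cultured cortical neurons and 16.9% in cultured hippocampal neurons.

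**Figure D1:**
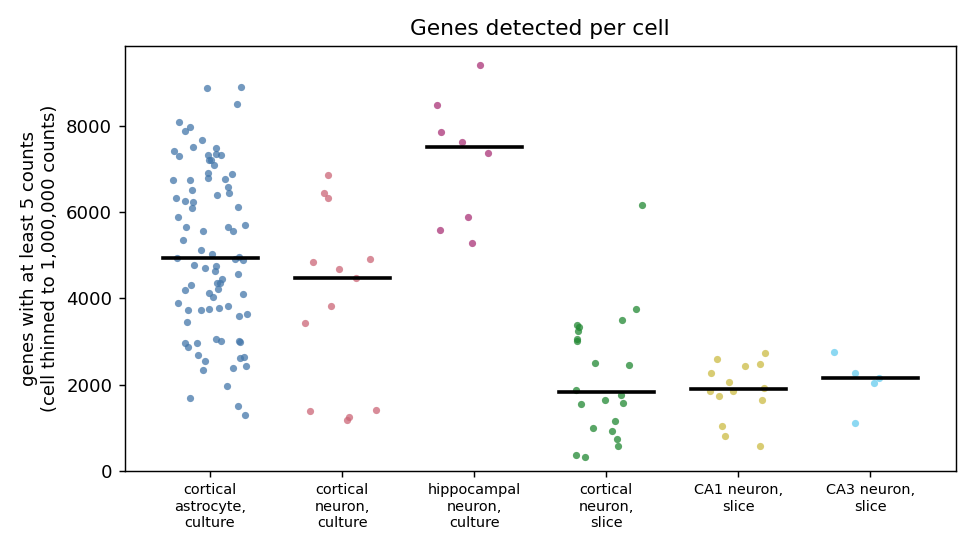
Genes with at least 5 counts per cell after thinning to 1000000 counts, for each cell (points, shifted sideways for visibility) in the 6 groups, with the group median as a bar. The bars of the 3 slice groups lie at 1819, 1887 and 2159 genes, against 4465 to 7515.5 genes in the 3 cultured groups.

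Marker genes were compared with the cell type in the labels. In 86 of 86 cultured astrocytes (100%, 95.8 to 100%) a larger percentage of the 20 astrocyte markers than of the 20 neuron markers was detected, with medians of 70% and 20% of the markers. The same held for 3 of 13 cultured cortical neurons (23.1%, 5.04 to 53.8%), 2 of 22 cortical slice neurons (9.09%, 1.12 to 29.2%) and none of the 8 cultured hippocampal neurons (0%, 0 to 36.9%), 14 CA1 neurons (0%, 0 to 23.2%) or 5 CA3 neurons (0%, 0 to 52.2%). Cultured cortical neurons had medians of 40% of the astrocyte and 65% of the neuron markers, cultured hippocampal neurons 32.5% and 97.5%, and cortical slice neurons 25% and 62.5%. No cell was moved or left out on this ground.

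**Figure D2:**
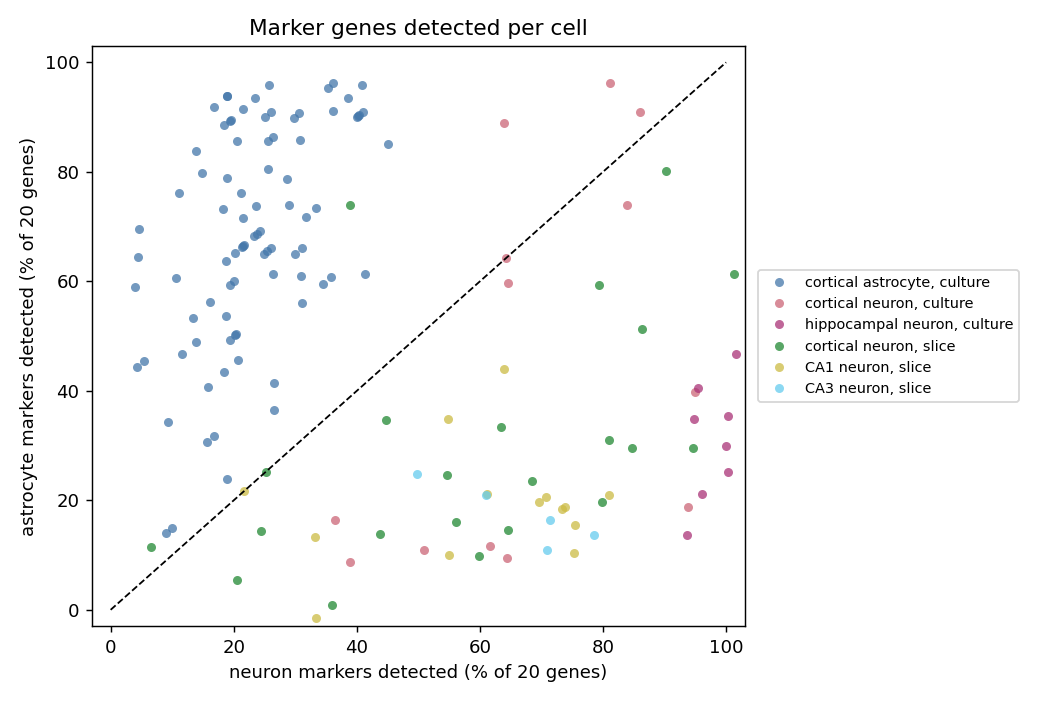
Percentage of the 20 astrocyte markers (vertical axis) against the percentage of the 20 neuron markers (horizontal axis) detected in each cell at the common depth, coloured by group, with a dashed line of equal percentages. Each point is shifted by up to 1.8 percentage points along the direction of the line, so that none crosses it: the 86 astrocytes lie above the line, as do 3 cultured and 2 slice cortical neurons.

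The comparison of cultured cortical astrocytes with cultured cortical neurons asked how these cell types of the same region differed. Neuronal genes were higher in neurons. Dcx, which encodes the microtubule-binding protein doublecortin of young neurons (chromosome X, 143855842 to 143933396 in GRCm38.p6) was at 936 CPM (932 to 940.2) against 0.261 CPM (0.234 to 0.291), in 12 of 13 cells (92.3%, 63.97 to 99.8%) against 1 of 86 (1.16%, 0.0294 to 6.31%) astrocytes. Snap25, a component of the complex that fuses synaptic vesicles with the membrane (chromosome 2, 136713439 to 136782428), was at 371 CPM (368 to 373) against 0.0353 CPM (0.0257 to 0.0472), in 11 of 13 cells (84.6%, 54.6 to 98.1%) against 0 of 86 (0%, 0 to 4.199%). Fn1, which encodes fibronectin (chromosome 1, 71585473 to 71653280), was higher in astrocytes, at 2059 CPM (2056 to 2061) against 54.2 CPM (53.2 to 55.2), in 81 of 86 cells (94.2%, 86.95 to 98.1%) against 2 of 13 (15.4%, 1.92 to 45.4%) neurons. The atypical cadherin Fat1 (chromosome 8, 44933100 to 45052257) was also higher, at 1351 CPM (1349 to 1353) against 19.2 CPM (18.6 to 19.8), in 84 of 86 cells (97.7%, 91.9 to 99.7%) against 2 of 13 (15.4%, 1.92 to 45.4%).

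All 20 measured neuron markers were at the higher level in neurons, with a median log2 ratio of -5.43, below all 10000 random lists of like expression. The median marker was detected in 80.8% of neurons and 10.5% of astrocytes. Examples were Elavl3, a neuronal RNA-binding protein (log2 ratio -6.29, 13 of 13 against 9 of 86 cells), and Stmn3, a member of the stathmin family (log2 ratio -8.05, 12 of 13 against 3 of 86 cells). All 12 inhibitory neuron markers were also at the higher level in neurons (median -5.48). Gad1, an enzyme of GABA synthesis, was at 1605 CPM against 0.353 CPM, 7 of 13 against 1 of 86 cells. The homeobox gene Dlx1 was at 234 CPM against 2.26 CPM, 9 of 13 against 5 of 86 cells. Slc32a1, the vesicular GABA transporter, was at 358 CPM against 0.0643 CPM, 6 of 13 against 0 of 86 cells. Other genes with large differences towards neurons were the endophilin gene Sh3gl2 (log2 ratio -8.87), Crmp1, a mediator of semaphorin signals (-8.26) and the transcription factor Bcl11a (-6.53). Cdk5r1, an activator of the kinase Cdk5, had a log2 ratio of -5.77, the synaptic vesicle GTPase Rab3a -5.73 and Gdap1 -8.22.

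Of 19 measured astrocyte markers, 16 were at the higher level in astrocytes and 16 in a larger share of them (median log2 ratio 0.77, above 98.0% of the random lists). The glutamate transporter Slc1a3 was at 1098 CPM (1097 to 1100.2) against 127 CPM (126 to 129), in 80 of 86 cells (93.02%, 85.4 to 97.4%) against 6 of 13 (46.2%, 19.2 to 74.9%) neurons. Sox9, a transcription factor of glial development, had a log2 ratio of 3.19 (80 of 86 against 6 of 13 cells), and Clu, which encodes clusterin, one of 0.23 (78 of 86 against 6 of 13 cells), which TMM scaling turned to -0.013 and DESeq2 scaling to -0.21. Of 18 genes reported in reactive astrocytes, 15 were higher in astrocytes (median 2.09). Among them, the hyaluronan receptor Cd44 was at 562 CPM against 19.2 CPM, 73 of 86 against 3 of 13 cells. Tm4sf1 was at 1019 CPM against 43.7 CPM, 77 of 86 against 4 of 13 cells. The ferroxidase Cp was at 313 CPM against 16.5 CPM, 70 of 86 against 4 of 13 cells. Markers of fibroblasts and meninges were likewise higher, 9 of 10 (median 3.38). Thbs1, thrombospondin, was at 1362 CPM against 47.8 CPM, 81 of 86 against 6 of 13 cells. The actin-binding Tagln was at 590.5 CPM against 257 CPM, 84 of 86 against 7 of 13 cells. Further genes higher in astrocytes were Tnc, which encodes tenascin C (log2 ratio 4.83, 73 of 86 against 1 of 13 cells), Mxra8 (5.63) and Msn, which links actin to the membrane (3.64). Spry1, an inhibitor of growth factor signalling, had a log2 ratio of 6.86, the LIM homeobox gene Lhx2 4.93, the peptidase Pepd 6.96, Ctnnal1 6.71 and Spata6 7.13.

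Cholesterol synthesis genes were higher in astrocytes for 13 of 15 members (median 1.69). Insig1, a sterol-regulated protein, was at 64.4 CPM against 5.86 CPM, 64 of 86 against 4 of 13 cells. The synthase Lss was at 33.5 CPM (33.2 to 33.8) against 0.00478 CPM (0.000121 to 0.0266, 1 count). Cell cycle genes were higher for 14 of 16 members (median 1.55). Pcna, the clamp of DNA replication, was at 442 CPM against 88.4 CPM, 74 of 86 against 8 of 13 cells. Tyms was at 35.99 CPM against 0.253 CPM, 26 of 86 against 0 of 13 cells. The cyclin Ccna2 was at 90.7 CPM against 4.77 CPM, 28 of 86 against 1 of 13 cells. Genes of mitochondrial DNA replication and transcription were higher for 11 of 16 members (median 1.42, above 95.7% of random lists). That was a weaker excess than for cholesterol synthesis (above 99.9%) and cell cycle genes (above 99.5%), and random lists reached medians of 1.42 and more. The mitochondrial DNA polymerase Polg was at 23.01 CPM against 5.25 CPM, 38 of 86 against 3 of 13 cells. The DNA-binding Ssbp1 was at 114 CPM against 42.4 CPM, 55 of 86 against 2 of 13 cells. The protease Lonp1 was at 64.2 CPM against 25.8 CPM, 62 of 86 against 6 of 13 cells. Glycolysis genes were at the higher level in the neurons for 10 of 18 members and in astrocytes for 8 (median -0.96, above 0.54% of random lists). Excitatory neuron markers were at the higher level in the neurons for 9 of 10 members (median -2.21, above 0.02% of random lists). Oligodendrocyte markers were at the higher level in the neurons for 8 of 9 members (median -3.23, below all random lists). Oligodendrocyte precursor markers had 3 of 8 members higher in astrocytes (median -2.504). Cspg4 was at 32.7 CPM against 4.44 CPM, 23 of 86 against 1 of 13 cells. Olig2 was at 38.5 CPM against 160.3 CPM, 48 of 86 against 5 of 13 cells. Gpr17 was at 0.00157 CPM (0.00019 to 0.00567, 2 counts) in astrocytes against 21.96 CPM in 3 of 13 neurons.

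These values come from 17473 measured genes, those with at least 10 counts in both groups together and a count in at least 3 cells. The 3 of 13 neurons that held more astrocyte than neuron markers stayed in. No alternative without them was run for this comparison, so their part in the values is not known. All astrocytes were basecalled with bcl2fastq2 v2.17, so only 7 of the 13 neurons share their version. Against those 7, the neuron markers had a median of -5.19, the astrocyte markers 1.41 with 18 of 19 higher, and the fibroblast and meningeal markers 3.36, whereas the oligodendrocyte precursor markers turned to 0.20. Among cells of 15 days alone (8 astrocytes of v2.17, 3 neurons of v1.8.4, so that age matched and basecalling did not), 8 of 19 astrocyte markers and 10 of 16 reactive genes were at the higher level in astrocytes, and the neuron markers had a median of -5.10, against 0.53 for all measured genes.

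Cortical neurons from acute slices were compared with those from culture. Genes of excitatory neurons were higher in slices: Nrgn, which encodes the postsynaptic calmodulin-binding protein neurogranin (chromosome 9, 37544493 to 37552745), was at 381 CPM (378 to 384) against 2.62 CPM (2.403 to 2.85), in 15 of 22 cells (68.2%, 45.1 to 86.1%) against 3 of 13 (23.1%, 5.04 to 53.8%) in culture. Genes of growing neurons were higher in culture. Nrep (chromosome 18, 33437019 to 33464365) was at 1654 CPM (1648 to 1659) against 96.9 CPM (95.3 to 98.5), in 13 of 13 cells (100%, 75.3 to 100%) against 4 of 22 (18.2%, 5.19 to 40.3%) in slices. Cnn3, an actin-binding calponin (chromosome 3, 121426541 to 121458205), was at 330.3 CPM (328 to 333) against 0.118 CPM (0.0701 to 0.187), in 12 of 13 cells (92.3%, 63.97 to 99.8%) against 0 of 22 (0%, 0 to 15.4%). Markers of microglia, another cell type, were also higher in the slice cells, with the fractalkine receptor Cx3cr1 (chromosome 9, 120048683 to 120068296) at 358 CPM (355 to 361) against 0.0287 CPM (0.0105 to 0.0624), in 9 of 22 cells (40.9%, 20.7 to 63.6%) against 0 of 13 (0%, 0 to 24.7%).

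Of 14 genes of axon growth and immature neurons, 11 were at the lower level in slices and all 14 were detected in a smaller share of slice cells (median log2 ratio -2.13, below all random lists). Detection was lower in slices for most lists, with a mean difference of -12.6 percentage points over all measured genes, and all 21 ribosomal protein genes and 28 of 29 respiratory chain genes were also in a smaller share of slice cells. The median axon growth member was detected in 31.8% of slice and 96.2% of cultured cells. Marcksl1, a substrate of protein kinase C, was at 56.04 CPM against 229 CPM, 3 of 22 against 13 of 13 cells. Sox4 went apart in level and detection, with 638 CPM against 487 CPM, 3 of 22 against 12 of 13 cells. Other genes higher in culture were Dpysl5, of the collapsin response mediator family (log2 ratio -6.78), the surface glycoprotein Cd24a (-6.22), the kinesin Kif21b (-2.51), the fatty acid binding protein Fabp5 (-2.42), Hn1 (-4.03), Ccdc124 (-4.56) and Bod1 (-2.83). Cell cycle genes were lower in slices for 15 of 16 members (median -3.03), as were 7 of 8 oligodendrocyte precursor markers (median -3.33) and 13 of 16 genes reported in reactive astrocytes (median -2.597). Without the 3 cultured and 2 slice cells holding more astrocyte than neuron markers, the cell cycle median was -0.16, with 3 of 14 members higher in slices. Pcna was at 52.6 CPM against 88.4 CPM, 5 of 22 against 8 of 13 cells. Mki67, a protein of dividing cells, was at 0.184 CPM against 107 CPM, 0 of 22 against 4 of 13 cells. The kinase Cdk1 was at 0.00657 CPM (0.000166 to 0.0366, 1 count) against 70.4 CPM in 4 of 13 cultured cells.

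Excitatory neuron markers were at the higher level in slices for 9 of 10 members (median 3.11, above 99.98% of random lists). The vesicular glutamate transporter Slc17a7 was at 93.6 CPM (92.1 to 95.1) against 2.95 CPM (2.72 to 3.19), in 12 of 22 cells (54.5%, 32.2 to 75.6%) against 3 of 13 (23.1%, 5.04 to 53.8%). Inhibitory neuron markers were at the lower level in slices for 9 of 12 members (median -1.83, above 2.44% of random lists). Gad1 was detected in 6 of 22 slice and 7 of 13 cultured cells. In slices, 16 cells had the title letter P (Gad1 in 1, Nrgn in 13) and 5 the letter F (Gad1 in 5, Nrgn in 1). No alternative by neuron subtype was run, so a difference in the subtypes collected cannot be told apart from one between slice and culture. Postsynaptic glutamate and GABA receptor genes were at the higher level for 13 of 18 members (median 1.13, above 99.3% of random lists) but in a larger share of slice cells for only 10. The AMPA receptor subunit Gria3 was at 837 CPM against 13.4 CPM, 15 of 22 against 4 of 13 cells. The NMDA receptor subunit Grin1 was at 22.8 CPM against 91.1 CPM, 9 of 22 against 8 of 13 cells. Slc4a10, a bicarbonate transporter, had a log2 ratio of 5.11, the potassium channel subunit Kcnf1 5.22, and the calcium sensor Syt7 1.78. Unc80, a subunit of a sodium leak channel, had one of 3.06, the non-coding RNA Snhg11 3.27, Trank1 5.79 and Fam126b 2.97. Immediate early and dissociation stress genes were at the higher level for 14 of 17 members (median 1.14) but in a larger share of slice cells for only 9. Fosb was at 49.6 CPM against 0.363 CPM, 6 of 22 against 0 of 13 cells. Junb was at 19.2 CPM against 1.66 CPM, 8 of 22 against 1 of 13 cells, and Nr4a1 at 37.7 CPM against 16.5 CPM, 7 of 22 against 1 of 13 cells.

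Beside these groups, all 12 microglia markers were at the higher level in slices (median 3.61, above all random lists). Aif1 was at 510.2 CPM against 0.354 CPM, 8 of 22 against 1 of 13 cells. The growth factor receptor Csf1r was at 174 CPM against 0.898 CPM, 6 of 22 against 1 of 13 cells. Oligodendrocyte markers were at the higher level in slices for 7 of 8 members (median 2.97) but in a larger share of cells for only 2. Mbp, myelin basic protein, was at 1157 CPM against 122 CPM, 10 of 22 against 8 of 13 cells. Cnp was at 37.1 CPM against 69.7 CPM, 4 of 22 against 7 of 13 cells, and the tight junction gene Cldn11 at 198 CPM against 27.4 CPM, 2 of 22 against 3 of 13 cells. Beta.s, the row of an adult haemoglobin beta chain, was at 364 CPM (361 to 367), in 11 of 22 slice cells. Its median over slice cells was 2.23 CPM and its highest value 6127 CPM. It had no count in the 13 cultured cortical neurons, and its summed level in slices was at least 25430.1-fold higher against the floor.

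Of the 13741 measured genes, the median log2 ratio was -0.24, and scaling by edgeR TMM or DESeq2 size factors moved it by 0.19 and 0.25. The cultured neurons of v2.17 and of v1.8.4 also differed in age (10 and 13 against 6 and 15 days). Within v2.17 (16 slice, 7 cultured cells) and v1.8.4 (8 and 6 cells), axon growth genes had medians of -2.57 and -1.36, excitatory markers 4.72 and 2.58, and receptor genes 1.25 and 1.26. In the same order, cell cycle genes had -1.42 and -3.51, stress genes 2.46 and 1.11, microglia markers 6.69 and 0.78 and oligodendrocyte markers 3.15 and 0.38. Without the 12 cells holding at least 25% of the microglia markers (13 and 10 cells left), axon growth genes had a median of -1.96 and excitatory markers 3.30. Against cultured neurons of 6 and 10 days, where the median of all measured genes was 0.72, the cell cycle median was 0.19 and that of receptor genes was 2.69, with 17 of 18 higher in level and in share. Receptor genes in a larger share of slice cells numbered 4 of 18 against cultured neurons of 13 and 15 days, and 6 of 18 within v2.17.

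CA1 neurons of the hippocampus were compared with cortical neurons, both from slices. Gad1 was detected in 4 of 14 CA1 and 6 of 22 cortical cells. No alternative by neuron subtype was run, so subtypes collected cannot be told apart from region. Zbtb20, a transcription factor needed for the identity of CA1 neurons (chromosome 16, 42875689 to 43634392), was at 329 CPM (325 to 333) against 22.8 CPM (22.02 to 23.5), in 9 of 14 cells (64.3%, 35.1 to 87.2%) against 2 of 22 (9.09%, 1.12 to 29.2%) cortical cells. The transcription factor Pou3f3 (chromosome 1, 42695768 to 42700210) was at 408 CPM (404 to 413) against 11.1 CPM (10.5 to 11.6), in 8 of 14 cells (57.1%, 28.9 to 82.3%) against 2 of 22 (9.09%, 1.12 to 29.2%). Nr2f1, which patterns the areas of the developing cortex (chromosome 13, 78188971 to 78198873), was higher in cortical cells, at 215 CPM (213 to 217) against 31.4 CPM (30.1 to 32.6), in 13 of 22 cells (59.1%, 36.4 to 79.3%) against 2 of 14 (14.3%, 1.78 to 42.8%) CA1 cells. Bmpr2, a receptor for bone morphogenetic proteins (chromosome 1, 59764279 to 59878081), was at 808 CPM (803 to 812) against 0.552 CPM (0.3997 to 0.744), in 12 of 22 cells (54.5%, 32.2 to 75.6%) against 0 of 14 (0%, 0 to 23.2%).

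Of 9 measured CA1 markers, 5 were at the higher level in CA1 (median log2 ratio 2.16, mean 0.61, median above 99.3% of random lists). Fibcd1 was at 43.4 CPM (41.96 to 44.9) in 4 of 14 CA1 cells (28.6%, 8.39 to 58.1%) and had no count in 22 cortical cells (0%, 0 to 15.4%), at least 2202-fold higher against the floor. Nov was at 0.514 CPM against 82.4 CPM, 1 of 14 against 6 of 22 cells. Of 15 cortical pyramidal markers, 7 were at the higher level in CA1 and 4 in a larger share of CA1 cells (median -0.17, which TMM and DESeq2 scaling turned to 0.34 and 0.55). Bcl11b, a transcription factor of deep-layer and hippocampal neurons, was at 649 CPM against 398 CPM, 8 of 14 against 7 of 22 cells. Cux2, of upper layers, was at 0.0128 CPM (0.000325 to 0.0716, 1 count) against 6.40 CPM in 6 of 22 cells.

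Further genes higher in CA1 were the actin regulator Wipf3 (log2 ratio 3.07), the mitochondrial carrier Slc25a23 (2.53), the autophagy protein Vmp1 (3.05), the chaperone Dnajb5 (2.04), Sash1 (6.49), the helicase Dhx33 (2.57) and Sh3glb2 (1.27). Higher in cortex were Fnbp1l (-6.19), the anion exchanger Slc4a3 (-4.12), the mitochondrial outer membrane channel Vdac3 (-5.75), the histone-binding Rbbp7 (-3.51), the repressor Etv6 (-7.45), Wdr6 (-4.81) and Sox9 (-6.32), which is an astrocyte marker. Kcnf1 was at 0.0128 CPM (0.000325 to 0.0716, 1 count) in CA1 against 54.6 CPM in 11 of 22 cortical cells.

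Ribosomal protein genes were at the higher level in CA1 for 20 of 21 members (median 1.16, above 99.9% of random lists). Rpl8 was at 1264 CPM against 399.9 CPM, 10 of 14 against 10 of 22 cells. Rpl10a was at 37.7 CPM against 55.1 CPM, 5 of 14 against 13 of 22 cells. Rpl27a, outside the list, was at 309 CPM against 57.9 CPM, 13 of 14 against 10 of 22 cells. These genes share sequence with many processed pseudogenes, so their counts are uncertain. Microglia markers were at the higher level in CA1 for 11 of 12 members (median 0.84). Tmem119 was at 551 CPM against 27.2 CPM, 5 of 14 against 2 of 22 cells. The receptor Trem2 was at 479 CPM against 268 CPM, 7 of 14 against 5 of 22 cells. The complement gene C1qa was at 107 CPM against 62.3 CPM, 6 of 14 against 6 of 22 cells. Oligodendrocyte markers were lower in CA1 for all 7 measured members (median -5.16). Ugt8a was at 0.231 CPM against 225 CPM, 0 of 14 against 4 of 22 cells, and Cnp at 0.0642 CPM against 37.1 CPM, 0 of 14 against 4 of 22 cells.

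The median of the 12666 measured genes was -0.37, and TMM and DESeq2 scaling moved it by 0.24 and 0.31. Within v2.17 (11 CA1 and 16 cortical cells, with 10 CA1 cells in the shares) and v1.8.4 (5 and 8 cells), CA1 markers had medians of 0.82 and -0.32. In the same order, cortical pyramidal markers had -0.80 and -1.02, ribosomal protein genes 0.34 and 2.11 and microglia markers 0.52 and 3.06. All measured genes had -0.21 and -1.89. The oligodendrocyte markers had a median of -5.73 within v2.17 and too few measured members within v1.8.4. Without the cells holding at least 25% of the microglia markers (7 CA1 and 13 cortical cells left), the medians of the CA1 markers and the ribosomal protein genes turned to -1.62 and -0.67.

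CA3 neurons were compared with CA1 neurons, both from slices. Nptx1, a neuronal pentraxin of excitatory synapses and a CA3 marker (chromosome 11, 119538719 to 119547820), was at 354 CPM (347 to 361) against 1.04 CPM (0.826 to 1.29), in 4 of 5 cells (80%, 28.4 to 99.5%) against 1 of 14 (7.14%, 0.181 to 33.9%) CA1 cells. Sgk1, a kinase induced by glucocorticoids (chromosome 10, 21882184 to 21999903), was at 1109.8 CPM (1097 to 1122) against 53.7 CPM (52.1 to 55.4), in 5 of 5 cells (100%, 47.8 to 100%) against 3 of 14 (21.4%, 4.66 to 50.8%). Adcy1, a calcium-stimulated adenylate cyclase (chromosome 11, 7063433 to 7178506), was higher in CA1, at 537 CPM (532 to 542) against 0.474 CPM (0.252 to 0.8098), in 10 of 14 cells (71.4%, 41.9 to 91.6%) against 0 of 5 (0%, 0 to 52.2%) CA3 cells. Ddn, a postsynaptic protein (chromosome 15, 98803782 to 98807925), was at 1125 CPM (1118 to 1133) against 0.692 CPM (0.417 to 1.08), in 10 of 14 cells (71.4%, 41.9 to 91.6%) against 0 of 5 (0%, 0 to 52.2%).

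Of 10 measured CA3 markers, 7 were at the higher level in CA3 and 8 in a larger share of its cells (median log2 ratio 1.78, above 96.0% of random lists). Cpne4, a calcium-dependent membrane-binding protein, was at 712 CPM against 0.334 CPM, 3 of 5 against 0 of 14 cells. Socs2, a suppressor of cytokine signals, was at 173 CPM against 1.63 CPM, 3 of 5 against 1 of 14 cells. Of 8 CA1 markers, 1 was at the higher level in CA3 (median -1.93, above 13.9% of random lists). That member, the transcription factor Neurod6, was at 364 CPM against 322 CPM, 5 of 5 against 3 of 14 cells. Fibcd1 was at 0.619 CPM against 43.4 CPM, 0 of 5 against 4 of 14 cells. Mpped1 was at 0.0364 CPM (0.000922 to 0.203, 1 count) against 396 CPM in 9 of 14 CA1 cells. All 8 measured inhibitory neuron markers were at the lower level in CA3 (median -7.22, below all random lists), with Gad1 detected in 4 of 14 CA1 and 0 of 5 CA3 cells. Over CA1 cells, Gad1 had a median of 0.915 CPM and 6295 CPM in the highest cell. A difference in the neuron subtypes collected therefore cannot be told apart from one between the fields.

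Further genes higher in CA3 were the transcription factor Klf10 (log2 ratio 7.30, 5 of 5 against 1 of 14 cells), Ank2, which anchors membrane proteins to the cytoskeleton (4.27), Msl2 (2.92), the non-coding RNA Mirg (8.43), Kctd4 (6.16) and Fam19a1 (7.86). Mndal, an interferon-inducible gene, was at 259 CPM in 5 of 5 CA3 cells against 0.0128 CPM (0.000325 to 0.0716, 1 count) in CA1. The non-coding Gt.ROSA.26Sor was at 89.8 CPM in 4 of 5 cells against 0.0385 CPM (0.00795 to 0.113, 3 counts). Higher in CA1 were the elongation factor gene Eef1b2 (-9.90, 12 of 14 against 0 of 5 cells), the chromatin remodeller Chd3 (-7.95), the surface protein Cd47 (-7.12) and Capza2, which caps actin filaments (-6.56). The phosphatase subunit Ppp1ca was at 173 CPM in 10 of 14 CA1 cells against 0.0364 CPM (0.000922 to 0.203, 1 count).

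Ribosomal protein genes were at the lower level in CA3 for 20 of 21 members (median -2.77, below all random lists) and in a smaller share of its cells for 12. Rplp0 was at 24.7 CPM against 929.8 CPM, 1 of 5 against 12 of 14 cells, and Rpl5 at 5.68 CPM against 673 CPM, 2 of 5 against 12 of 14 cells. Rps16 was at 41.3 CPM against 662 CPM, 1 of 5 against 13 of 14 cells. Microglia markers were at the lower level in CA3 for 11 of 12 members and in a smaller share of its cells for all 12 (median -8.11). Trem2 and C1qa had no count in CA3 and were at least 4385-fold and 979-fold higher in CA1 against the floor. Aif1 was at 0.0364 CPM (0.000922 to 0.203, 1 count) against 917 CPM in 7 of 14 CA1 cells.

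The median of the 9378 measured genes was -0.70, and TMM and DESeq2 scaling moved it by 0.19 and 0.37. Within v2.17 (4 CA3 and 11 CA1 cells, with 10 CA1 cells in the shares), CA3 markers had a median of 1.48 and CA1 markers -3.51. Ribosomal protein genes had -1.40 there and microglia markers -7.25, and v1.8.4 held 1 CA3 cell. Leaving out each CA3 cell in turn gave medians of 0.83 (without replicate 3) to 2.44 (without replicate 2) for CA3 markers and of -3.59 (without replicate 2) to -1.70 for CA1 markers. Ribosomal protein genes then had medians of -3.39 to -2.52, and Nptx1 a log2 ratio of 6.78 to 8.10. Without replicate 2, Klf10 stood at 4.23, Mirg at 5.83 and Ank2 at 2.73, and without replicate 3, Sgk1 at 3.16, Socs2 at 4.29 and Rplp0 at -9.4997. Without replicate 4, Mndal stood at 5.67, Fam19a1 at 5.95, Cpne4 at 7.68, Rps16 at -9.303 and Neurod6 at -0.396, and without replicate 1, Chd3 at -10.66. Without the CA1 cells holding at least 25% of the microglia markers (5 CA3 and 7 CA1 cells left), 13 of 21 ribosomal protein genes were higher in CA3, with a median of 0.82.

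Cultured hippocampal neurons were compared with cultured cortical neurons. Genes of inhibitory neurons were higher in the hippocampal cells. Reln, which encodes the secreted glycoprotein reelin (chromosome 5, 21884454 to 22344705), was at 2042 CPM (2032 to 2051) against 0.2102 CPM (0.153 to 0.282), in 8 of 8 cells (100%, 63.1 to 100%) against 0 of 13 (0%, 0 to 24.7%) cortical cells. Npy, neuropeptide Y, was at 2673 CPM (2662 to 2684) against 86.98 CPM (85.7 to 88.3), in 8 of 8 cells (100%, 63.1 to 100%) against 4 of 13 (30.8%, 9.09 to 61.4%). Sparc, a matrix-binding glycoprotein (chromosome 11, 55394159 to 55420080), was higher in the cortical cells, at 1559 CPM (1553 to 1564) against 0.148 CPM (0.0787 to 0.253), in 9 of 13 cells (69.2%, 38.6 to 90.9%) against 0 of 8 (0%, 0 to 36.9%) hippocampal cells. Ccnd2, a cyclin of the first phase of the cell cycle (chromosome 6, 127125162 to 127152188), was also higher there, at 731 CPM (727 to 735) against 2.172 CPM (1.88 to 2.503), in 11 of 13 cells (84.6%, 54.6 to 98.1%) against 2 of 8 (25%, 3.19 to 65.1%).

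Of 12 inhibitory neuron markers, 8 were at the higher level in hippocampal cells and 10 in a larger share of them (median log2 ratio 2.504, above all random lists). The median marker was detected in 100% of hippocampal and 30.8% of cortical cells, where detection over all measured genes was higher in hippocampal cells by a mean of 23.97 percentage points. The LIM homeobox gene Lhx6 was at 227 CPM against 30.2 CPM, 8 of 8 against 1 of 13 cells. The calcium-binding parvalbumin, Pvalb, was at 299 CPM against 0.525 CPM, 5 of 8 against 0 of 13 cells. Neuron markers were higher for 16 of 20 members (median 1.13). The neurofilament gene Nefm was at 192 CPM against 5.66 CPM, 7 of 8 against 1 of 13 cells. Nefl, another, was at 409 CPM against 28.5 CPM, 7 of 8 against 3 of 13 cells. The neuronal enolase Eno2 was at 572 CPM against 72.2 CPM, 8 of 8 against 3 of 13 cells. Voltage-gated channel genes were higher for 12 of 16 members (median 1.79). The sodium channel Scn1a was at 187 CPM against 6.74 CPM, 7 of 8 against 1 of 13 cells. The potassium channel Kcnc1 was at 281 CPM against 16.7 CPM, 8 of 8 against 3 of 13 cells. None of the 9 hippocampal pyramidal markers was at the higher level in hippocampal cells, and 4 were in a larger share of them (median -1.63, above 1.11% of random lists). Meis2 was at 1.06 CPM against 918 CPM, 0 of 8 against 10 of 13 cells. Zbtb20 was at 9.93 CPM against 136 CPM, 2 of 8 against 7 of 13 cells. Nrp2, a semaphorin receptor, was at 65.8 CPM against 134 CPM, 6 of 8 against 4 of 13 cells.

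Nuclear genes of the respiratory chain were at the higher level in hippocampal cells for 28 of 29 members (median 0.99, above 99.93% of random lists). Uqcrc1 was at 268 CPM against 93.8 CPM, 8 of 8 against 7 of 13 cells. Ndufs1 was at 324 CPM against 116 CPM, 8 of 8 against 8 of 13 cells, and Ndufa1 at 538 CPM against 333 CPM, 8 of 8 against 8 of 13 cells. Cholesterol synthesis genes were higher for 13 of 15 members (median 2.1698). Insig1 was at 106 CPM against 5.86 CPM, 8 of 8 against 4 of 13 cells. Mvd was at 109 CPM against 125 CPM, 7 of 8 against 1 of 13 cells, and Lss at 91.1 CPM in 6 of 8 cells against 0.00478 CPM (0.000121 to 0.0266, 1 count). Further genes higher in hippocampal cells were the deacetylase Hdac9 (log2 ratio 5.45), the adhesion protein Flrt2 (5.17), the vesicle protein Vamp1 (4.82), and the kinesin light chain Klc2 (4.70). They also included the mitochondrial fatty acid enzyme Mecr (4.58), Errfi1 (4.30), Lnx1 (4.24), the kinase Prkx (4.74) and Tstd3 (6.41).

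Markers of other cell types were also lower in hippocampal cells: microglia markers for 9 of 10 members (median -4.15), all 8 oligodendrocyte markers (median -3.34) and all 8 oligodendrocyte precursor markers (median -3.17). All 21 ribosomal protein genes were at the lower level (median -1.41). All 19 astrocyte markers were at the lower level in hippocampal cells, although 6 were in a larger share of them (median -4.11, below all random lists). The astrocyte filament gene Gfap was at 0.0682 CPM against 100.4 CPM, 0 of 8 against 7 of 13 cells. Acsbg1 was at 0.625 CPM against 98.2 CPM, 0 of 8 against 6 of 13 cells, and Clu at 76.05 CPM against 220.0 CPM, 8 of 8 against 6 of 13 cells. Higher in cortical cells were also Synpr, a synaptic vesicle protein (-9.88, 10 of 13 against 0 of 8 cells), Trim59 (-7.13), the cyclin Ccnd1 (-6.66), Csrp1 (-4.63) and the smooth muscle actin Acta2 (-6.13). Nes, an intermediate filament of neural progenitors, was at 171 CPM in 8 of 13 cortical cells against 0.0227 CPM (0.00275 to 0.0822, 2 counts). Cdkn1a, an inhibitor of cell division, was at 107 CPM in 8 of 13 cortical cells and had no count in hippocampal cells, at least 3124-fold higher against the floor.

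The median of the 13485 measured genes was 0.15, and TMM and DESeq2 scaling moved it by -0.17 and -0.16. Within v2.17 (8 hippocampal and 7 cortical cells), inhibitory markers had a median of 2.13, neuron markers 1.34, astrocyte markers -4.20, and hippocampal pyramidal markers -1.71. Voltage-gated channels had a median of 1.71, respiratory chain genes 0.85 and cholesterol synthesis genes 2.61. Region and strain label differ together between these groups and cannot be told apart. The groups also differed in transmitter genes. Gad1 was detected in 8 of 8 hippocampal and 7 of 13 cortical cells, and Slc17a7 in 2 of 8 and 3 of 13. A difference in the neuron subtypes collected therefore cannot be told apart from region and strain label either. Against the 3 cortical neurons of 15 days, which match the hippocampal cells in age but were basecalled with v1.8.4, all 10 measured inhibitory markers were at the higher level, with a median of 4.26 against 0.74 for all measured genes. Without the 3 cortical cells holding more astrocyte than neuron markers, the astrocyte marker median was -2.78. Without the 2 hippocampal libraries of letter D (6 and 13 cells), inhibitory markers had a median of 2.59, neuron markers 1.19, astrocyte markers -4.88, respiratory chain genes 0.69 and hippocampal pyramidal markers -2.83.

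**Figure D3:**
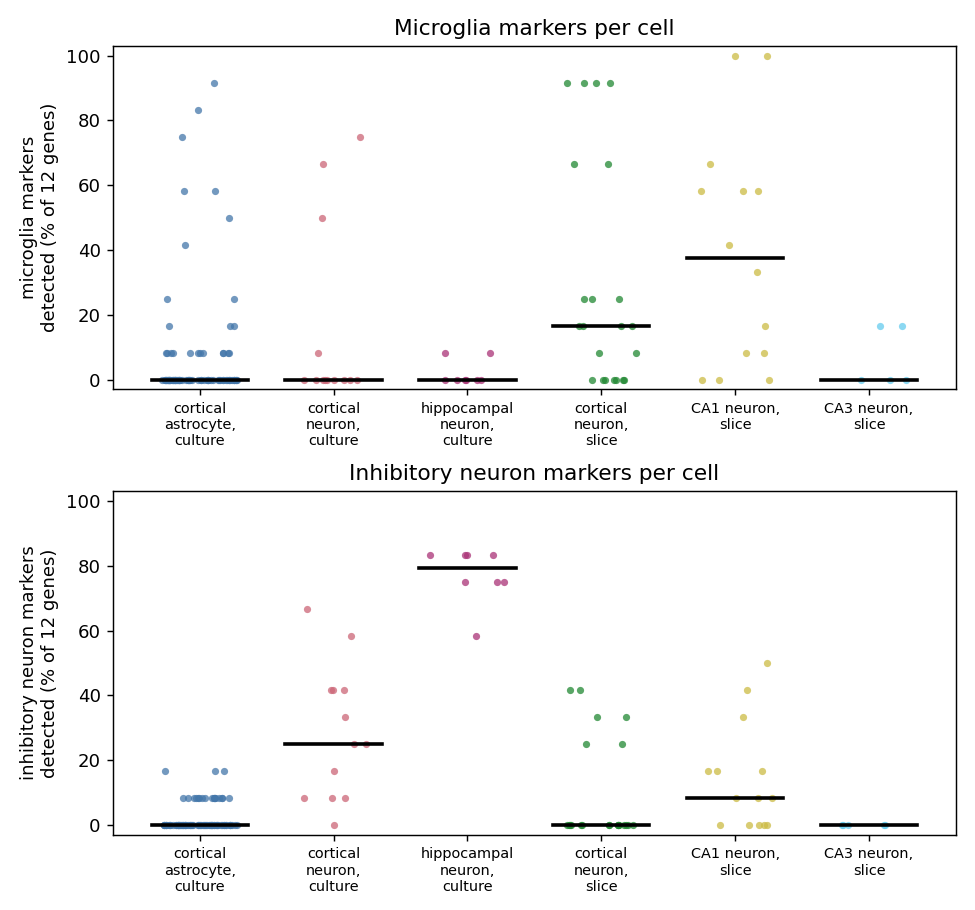
Percentage of the 12 microglia markers (upper panel) and of the 12 inhibitory neuron markers (lower panel) detected in each cell at the common depth, by group, with points shifted sideways for visibility and bars at the group medians. The 8 cultured hippocampal neurons lie between 58.3% and 83.3% of the inhibitory markers, and 12 of 41 slice cells hold at least 7 of the 12 microglia markers.

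Cultured astrocytes of 15 days (8 cells) were compared with those of 12 days (70 cells). Spata1 (chromosome 3, 146457202 to 146499793) was higher at 15 days, at 73.3 CPM (71.6 to 74.97) against 8.12 CPM (7.94 to 8.29), in 6 of 8 cells (75%, 34.9 to 96.8%) against 9 of 70 (12.9%, 6.05 to 23.01%) at 12 days. Ldb1, a cofactor of LIM homeobox proteins (chromosome 19, 46031525 to 46048145), was at 36.3 CPM (35.1 to 37.5) against 3.04 CPM (2.94 to 3.15), in 6 of 8 cells (75%, 34.9 to 96.8%) against 13 of 70 (18.6%, 10.3 to 29.7%). Fbl, which encodes the nucleolar protein fibrillarin (chromosome 7, 28168893 to 28179269), was higher at 12 days, at 28.9 CPM (28.6 to 29.3) against 5.401 CPM (4.95 to 5.88), in 43 of 70 cells (61.4%, 49.03 to 72.8%) against 1 of 8 (12.5%, 0.316 to 52.7%) at 15 days. Cercam had a log2 ratio of 2.13 and the mitochondrial protein Timmdc1 one of 2.27, while Fbxl5, which senses iron, had -1.82, Hps5 -4.80 and Tceal5 -2.29.

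Of 18 genes reported in reactive astrocytes, 7 were at the higher level and 5 in a larger share of cells at 15 days (median -0.29, above 16.2% of random lists). The heat shock protein Hspb1 was at 8.53 CPM against 23.5 CPM, 2 of 8 against 35 of 70 cells. The sphingosine receptor S1pr3 was at 35.99 CPM against 40.4 CPM, 4 of 8 against 22 of 70 cells. Cell cycle genes were in a larger share of 15-day cells for 15 of 16 members but at the higher level for 7 (median -0.20, turned to 0.03 by DESeq2 scaling). The cyclin Ccnb2 was at 149 CPM against 63.2 CPM, 5 of 8 against 17 of 70 cells, and Ccna2 at 53.8 CPM against 70.9 CPM, 5 of 8 against 18 of 70 cells. Microglia markers were at the higher level for 10 of 11 members (median 1.81, above 99.99% of random lists). The protease Ctss was at 319 CPM against 89.9 CPM, 4 of 8 against 8 of 70 cells. The complement gene C1qb was at 20.7 CPM against 7.19 CPM, 3 of 8 against 7 of 70 cells. Interferon response genes were at the higher level for 8 of 11 members (median 0.29, above 88.7% of random lists). Ifit1 was at 21.6 CPM against 6.77 CPM, 3 of 8 against 4 of 70 cells.

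There were 16569 measured genes, and all cells had the same basecalling version. Between 14 days (5 cells) and 12 days the microglia marker median turned to -3.03, and no cell cycle gene was at the higher level. The 7-day cells (3 cells) carried the other strain label, and against 12 days they had all 16 cell cycle genes at the higher level and a microglia marker median of -2.58, against -0.63 for all measured genes.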

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

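The tests of technical explanations in this part were chosen after the results they weigh had been seen, and none was planned.

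The 62 sets examined were each the 5 or 8 cells of a group on a gene list, depth, genes detected or the share of the 50 highest genes. In 5 sets a cell stood apart from the rest. The rule was set for a rate of 1 in 20, which would give about 3.1. That rate assumes continuous values and does not hold for percentages of short gene lists. Where all other cells are at 0%, a single detected gene is enough to stand apart, so the number was not weighed against chance. Cultured hippocampal neuron 7 had 58.3% of the inhibitory neuron markers, with the other 7 cells at 75% to 83.3%. Cultured hippocampal neuron 3 had 9.09% of the endothelial and pericyte markers, with 0% in the other cells. The same cell had 6.67% of the cortical pyramidal markers, with the nearest cell at 33.3%. CA3 neuron 5 had 0% of the axon growth and immature neuron genes, with the nearest cell at 35.7%. CA3 neuron 1 had 5.56% of the genes reported in reactive astrocytes, with 0% in the other 4 cells.

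Microglia markers were detected in slice cells labelled as neurons. Of 42 slice cells, 18 lay above 1114 CPM of summed markers, 10% of the highest cultured cell (11140 CPM), and the highest slice cell reached 18278 CPM. This argues against reads strayed from cultured libraries as the whole source. Levels in CPM do not account for the greater depth of cultured libraries, so a smaller part is not excluded. The markers came together: 12 of 41 slice cells held at least 7 of the 12 markers, against at most 5 in 1000 shuffles. By group, these were 6 of 22 cortical (27.3%, 10.7 to 50.2%), 6 of 14 CA1 (42.9%, 17.7 to 71.1%) and 0 of 5 CA3 cells (0%, 0 to 52.2%). The shuffles did not keep the number of genes detected per cell, which ran from 324 to 6160 in cortical slice cells. Members of other lists could come together beyond such shuffles too, so the excess does not single out microglial RNA. RNA of a microglial cell collected with the neuron is a candidate explanation. Ctss was at 809 CPM in cortical, 1134 CPM in CA1 and 3.90 CPM in CA3 slice cells and 293 CPM in cultured cortical neurons. In the same order, C1qc was at 317, 425, 0.874 and 31.1 CPM. Both genes belong to the 12 markers, so their levels restate the pattern and add no further evidence. Outside the list, Cst3, an abundant microglial transcript, was no higher in cortical slice cells than in culture, at 960.03, 6122, 45.3 and 1097 CPM. Whether some cells were microglia rather than neurons stays open, as 8 of 17 cells with at least 25% of the markers held a larger percentage of neuron markers (47.1%, 22.98 to 72.2%, by a rule set after this value was seen), and a biological difference between regions was not tested.

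Slice neurons of the cortex had fewer genes detected than cultured ones, a median of 1819 against 4465. A difference in depth is argued against as the whole cause, since the ratio of medians was 44.7% before and 40.7% after thinning. A few genes taking most of the counts are argued against likewise, with 48.5% after the 50 highest genes of each cell had been taken out (20 and 13 cells), as is basecalling, with 34.4% within v2.17 (16 and 7 cells) and 79.3% within v1.8.4 (8 and 6 cells). The quartiles of the groups overlap, 1031.75 to 3194.25 and 1412 to 4925 genes. A lower amount of RNA collected from slices could contribute and, like a biological difference between slice and culture, stays open and untested.

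Xist, which is expressed from the inactive X chromosome of females, and Y-linked transcripts were both above 5 CPM in 8 of 86 astrocyte libraries (9.30%, 4.10 to 17.5%), and in none of the other groups' cells. Of the rest, 21 astrocytes had Xist alone, 47 the Y-linked transcripts alone and 10 neither. In 5 of the 8 the lesser signal exceeded 1% of the highest level in any library, from 1.19% to 11.5%. This does not decide whether reads strayed from other libraries. Stray reads follow the counts of their source, the levels were compared in CPM, and astrocyte totals ran from 1089800 to 38680700 counts. RNA of more than 1 cell collected together may be the source, but 5 of the 8 lay above the astrocytes' median of genes detected, which does not decide it. The design gives no biological explanation, and none was tested.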

How the results depend on the processing

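The alternatives without cells by marker content, without cells with over 50% of counts on 50 genes, and without the hippocampal libraries of title letter D were chosen after the results were seen, as was the sum of repeat libraries, whose alternative here keeps each library as a cell as first planned and is counted with the added values, and all others were planned. No paired analysis was possible because the labels do not link cells of different groups. The share of mitochondrial counts and its alternatives, totals of nuclear genes alone, and v1.8.4 alone (astrocytes, CA3, cultured hippocampal neurons) were not run for lack of rows or cells, and no cell lay below 100000 counts. The percentage of cells with more astrocyte than neuron markers stayed within its interval in all 18 planned and 3 added values. Of the planned values, 629 of 716 member counts stayed within 1.5 times, and 340 of 430 list medians and 1739 of 2299 gene ratios moved by at most 1.5 times. Of the added values, 172 of 190, 78 of 95 and 451 of 524 did. Counting only log2 ratios of at least 1 in size, 5 medians and 23 gene ratios reversed among the planned values and 3 and 2 among the added ones. Smaller ratios that changed sign are not in these numbers. Depth limits the thinned shares to genes of about 5 CPM and above. For the results that follow, the cause was not tested.

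In astrocytes against cultured neurons, 1 of 20 neuron markers was at the higher level in astrocytes without the deepest cells and at 12 to 15 days, and the number in a larger share of cells was 2 within v2.17 and at 10 counts and 0 at 15 days and at 12 to 15 days. Astrocyte markers numbered 8 by level and 4 by share at 15 days, and 8 by share at 12 to 15 days. Within v2.17, the oligodendrocyte precursor median was 0.20 and Olig2 stood at 1.12. At 15 days, where all neurons were of v1.8.4 and the median of all measured genes was 0.53, Tagln was at -1.24, Ssbp1 at -1.92 and Polg at -0.27.

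In slice against culture, postsynaptic receptor genes in a larger share of slice cells numbered 6 within v2.17, 4 against neurons of 13 and 15 days and 17 against 6 and 10 days. Within v1.8.4, Nr4a1 was at -0.43 and Cldn11 at -5.52. Against 6 and 10 days, the cell cycle median was 0.19, Nr4a1 -0.21 and Mki67 0.24, all below the 0.72 of all measured genes there.

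In CA1 against cortex, Rpl8 was at -0.40 within v2.17. Within v1.8.4, 3 CA1 markers were higher by level and 3 by share, with a median of -0.32, above the -1.89 of all measured genes there. At 1 count, 7 cortical pyramidal markers were in a larger share of CA1 cells. Without cells with microglia markers, 3 CA1 markers (median -1.62) and 4 cortical pyramidal markers were higher in CA1, the ribosomal median was -0.67 and Rpl8 was at -2.73.

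In CA3 against CA1, the number of CA1 markers at the higher level in CA3 was 0 within v2.17 and without CA3 replicate 4 (range 0 to 1 without each CA3 cell). The number in a larger share was 2 at 1 count, 2 not thinned and 2 without cells with microglia markers, where the ribosomal median was 0.82. In hippocampal against cortical cultures, 1 hippocampal pyramidal marker was higher at 15 days (median of all measured genes 0.74) and 2 without cells with more astrocyte than neuron markers, where Clu was at 0.079.

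In astrocytes by age, the reactive genes at the higher level at 15 days numbered 4 without the deepest cells, and those in a larger share 9 at 1 count, 8 at 10 counts and 9 not thinned. For 14 against 12 days, 11 reactive genes were in a larger share, cell cycle genes numbered 0 by level and 4 by share, and the microglia median was -3.03. There, Spata1 was at -1.75, Hspb1 1.97, Ccnb2 -6.00, Ctss -6.40, C1qb -3.03 and Ifit1 -0.044. For 7 against 12 days, 3 reactive and 16 cell cycle genes were at the higher level, and the microglia median was -2.58, against -0.63 for all measured genes. There, Spata1 was at -2.36, Cercam -1.71, Ldb1 -0.76, Timmdc1 -1.30, Fbl 0.0599, Ctss -6.51, C1qb -3.03 and Ifit1 -2.79.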

Other observations

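The values in this part were chosen after the data had been seen, and no test was run on them. Transmitter genes differed between the groups of neurons. In cultured hippocampal neurons, genes of GABA synthesis and transport were detected in all 8 cells: Gad1 at 8856 CPM (8836 to 8875), Gad2 at 4968 CPM (4954 to 4983) and Slc32a1 at 1014 CPM (1007 to 1020.4). The glutamate transporter Slc17a7 was detected in 2 of these 8 cells (25%, 3.19 to 65.1%) at 9.64 CPM, and Slc17a6 in 0 of 8 (0%, 0 to 36.9%). In CA3 neurons, Slc17a7 was detected in 4 of 5 cells (80%, 28.4 to 99.5%) at 454 CPM, with 4874 CPM in the highest cell. In CA1 neurons, Gad1 was detected in 4 of 14 cells (28.6%, 8.39 to 58.1%) at 686 CPM, with 6295 CPM in the highest cell.

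Cortical slice neurons carry letters in their titles that the labels do not explain. The 5 cells with the letter F all had Gad1 (100%, 47.8 to 100%), at 4481 CPM, and Slc32a1, at 396 CPM. Among the 16 cells with the letter P, Gad1 was detected in 1 (6.25%, 0.158 to 30.2%), at 49.99 CPM. Nrgn, by contrast, was detected in 1 of 5 F cells (20%, 0.505 to 71.6%) and 13 of 16 P cells (81.3%, 54.4 to 95.95%), and Slc17a7 in 1 of 5 and 10 of 16. Camk2a, another excitatory neuron marker, was detected in a larger share of F cells, 4 of 5 against 8 of 16 P cells (155 against 200 CPM).

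Beta.s, the row of an adult haemoglobin beta chain of red blood cells, was detected in 11 of 22 cortical slice cells (50%, 28.2 to 71.8%) at 364 CPM, with 6127 CPM in the highest cell. It was detected in 3 of 14 CA1 cells (21.4%, 4.66 to 50.8%) at 142 CPM and 0 of 5 CA3 cells (0%, 0 to 52.2%). In culture it was detected in 10 of 86 astrocytes (11.6%, 5.72 to 20.3%) at 4.88 CPM, and in 0 of 13 cortical neurons (0%, 0 to 24.7%).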
